A study of Mus musculus with 6 samples.

How the data were processed

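Messenger RNA libraries were made from 1000 ng of RNA of RAW264.7 macrophages carrying the inducible oncoprotein construct, selected with hygromycin B at 70 µg/mL for 7 days. Per the labels, serum was withdrawn 24 hours before RNA extraction, all samples had an RNA integrity number above 9.5, libraries had 9 PCR cycles, and about 20 M single-end reads were sequenced per sample. There were 3 vehicle samples and 3 samples given 100 nM 4-OHT, lettered A, B and C in each group, all of day 3. The labels do not say whether the letters mark a shared culture or day.

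The authors' processing notes name bcl2fastq 2.20, Trimmomatic 0.35, STAR 2.5.1b, RSEM (with no version) and DESeq2 1.18.1, with builds GRCm38 and mm10. The role of each tool, the annotation, the handling of strands and of reads that fit several genes, and any filter are not stated, so values of overlapping genes and of close gene families are uncertain. The deposited table has 50600 lines after its header, of which 1 holds no values and was not used, leaving 50599 genes. Coordinates are those of the table, and 92.6% of its gene identifiers, 46843, lie at the same place in GENCODE M21.

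The deposited signal per gene and sample is a gene count divided by a size factor of its library, as the values themselves show and as DESeq2, which the authors name, would give. In each column every positive value (100%) is a whole multiple of a single step within 1e-06. The step is 0.975, 0.989 and 0.721 in vehicle replicates A, B and C and 1.13, 1.09 and 1.13 in 4-OHT replicates A, B and C, the inverse of size factors of 1.03, 1.01, 1.39, 0.883, 0.916 and 0.882. Dividing by the step gave whole reads. For vehicle replicate B an automatic check of units did not accept the recovery, because a step this close to 1 can also come from rounding. Its values carry decimals and are not whole numbers, and its recovered reads were used all the same, but count models were also run without it. The recovered reads serve for depth, counting intervals, the filter on low counts and alternative count models. The log2 fold change of 4-OHT over control and its standard error in the deposited table are the authors' own, named so per the file headers. The deposited p-value and adjusted p-value columns are also the authors' and were used here only for comparison. Of 16499 genes with an adjusted p in that table, 7026 lie under 0.05.

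Recovered reads ranged from 11629150 to 15943722 per library, and deposited totals were 11.3, 11.7 and 11.5 (vehicle A, B and C) and 13.8, 14.4 and 14.5 (4-OHT A, B and C) in units of 1e+06. Chi-square per degree of freedom between replicate pairs, over genes with 20 or more reads, was 3.07 to 12.2, so replicates spread more than counting error alone gives and 0 pairs were copies of each other. Counting intervals of ratios are exact binomial (Clopper-Pearson) at 95%, and floors stand for 3 reads over the group.

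The plan made before the data were examined was an edgeR test on counts, with limma on log2(value + 1) if the table held no counts. Since the deposited values are not counts, limma 3.58.1 in R 4.3.3 was used, with a mean-variance trend, a pseudocount of 1 and group as the only term, on the deposited values. Genes were tested if they passed edgeR 4.0.16 filterByExpr (minimum count 10) on recovered reads, which left 11828. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and at least 2-fold means an absolute log2 fold change of 1 or more. All tests of genes and lists are two-sided. Depth and error of values are given as means with the SD of 3 samples, and log2 changes with the standard error of the model.

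The 28 gene lists were fixed before the data were examined. They cover ERK feedback, E2F targets, mitosis, CDK inhibitors, p53 targets, secreted factors of senescence in a pair of lists, cholesterol synthesis, LXR targets, lipid uptake, interferon-stimulated genes, lysosome and autophagy, osteoclast differentiation, macrophage identity, M1-like and M2-like activation, glycolysis, oxidative phosphorylation, the ATF4 and unfolded protein response, ribosome biogenesis, chromatin and lamina genes of senescence, oestrogen receptor targets, mitochondrial transcripts, and markers of fibroblasts, lymphocytes, neutrophils and mast cells, dendritic cells, and epithelial and endothelial cells. There are 16 genes that stand in more than a single list. Lists with 3 or more tested genes, 24 in all, were tested with camera at a preset inter-gene correlation of 0.01 on log2(value + 1), where the plan for counts was log2 CPM, adjusted over the 24 lists. Camera with an estimated correlation and fry were alternatives.

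Named genes followed a rule fixed in advance. It takes the 12 highest and 12 lowest log2 fold changes among called genes with a mean of 10 or more CPM (reads scaled to the library total) and no overlap between groups, leaving out unnamed gene models and pseudogenes. It adds up to 4 members of each list with the smallest limma p (the plan said edgeR) and 28 genes chosen for the biology, such as Esr1, Cdkn1a, Cdkn2a and Il6. Some genes the rule takes are not reported here. Genes outside the rule are said to be chosen after their values were seen.

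The procedure was tested on simulated data made from these libraries with known changes. Of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold it called 84%, 93.9%, 100% and 100%, and 5.09% of its calls were false. A list of 25 genes lowered by 0.5 on the log2 scale was called, and 0 of 20 unchanged lists were. In the simulation genes varied independently of one another, and 11556 of the 11778 tested were unchanged. It therefore tests neither the preset correlation of the list test nor the scaling when most genes change.

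Alternatives were other scalings (TMM, total counts), pseudocounts of 0.5 and 4, no filter, a CPM of 1 or more in 3 libraries, limma without the trend or robust, an adjusted p under 0.01, a block for the replicate letter, each library left out in turn, and edgeR, DESeq2 1.42.0 and limma-voom on recovered reads. The planned scaling by DESeq2 size factors is the deposited scaling itself, so TMM took its place. Reads from the construct could not be told from those of Esr1, and raw sequence reads were not used here.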

Results

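RNA was sequenced from RAW264.7 cells, a mouse macrophage line, that carried a retroviral construct of an oncoprotein fused to the oestrogen receptor, switched on by 4-hydroxytamoxifen (4-OHT). The cells were given 100 nM 4-OHT or ethanol vehicle and collected on day 3, with 3 samples in each group. The deposited table lists 50599 genes with 1 value per sample, each a gene count divided by a size factor. Counts recovered from it came to 11629150, 11822117 and 15943722 reads in vehicle replicates A, B and C, and to 12140978, 13213543 and 12798474 reads in 4-OHT replicates A, B and C. Between 17278 and 18346 genes had at least 1 read in a library. The principal component that took 91.3% of the variance separated the vehicle libraries from the 4-OHT libraries. The next took 2.90% and ordered both groups by replicate letter, A, B and C.

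The comparison of 4-OHT with vehicle asks which transcripts differed 3 days after activation of the oncoprotein, in cells the labels describe as senescent. No cells without the construct were given 4-OHT, so effects of the drug itself cannot be told from those of the oncoprotein. With 4-OHT, 19 of 26 ERK feedback genes, 14 of 16 secreted cytokines and chemokines, 16 of 22 secreted proteases and growth factors, 30 of 30 interferon-stimulated genes and 23 of 31 lysosomal genes were higher, and 33 of 40 DNA replication, 31 of 31 mitosis, 22 of 22 ribosome biogenesis and 14 of 15 chromatin and lamina genes were lower. These counts are of tested genes, while the secretory lists held 24 and 36 genes. All lists named here passed by camera with a preset correlation. None passed with an estimated correlation, where their adjusted p lay between 0.293 and 0.433. Plau, the urokinase-type plasminogen activator, rose 19.6-fold, from 5300 ± 130 to 104055 ± 14023 normalized counts (SD, n = 3 per group). Dusp6, a phosphatase that removes the activating phosphates of ERK, rose 17.8-fold, from 139 ± 15.02 to 2480 ± 318 normalized counts. Bub1b, a spindle checkpoint kinase, fell to 0.403 times its vehicle level, from 1102 ± 50.7 to 445 ± 14.3 normalized counts. Abca1, the transporter that exports cholesterol from macrophages, fell to 0.123 times its vehicle level, from 1225 ± 109 to 151 ± 26.2 normalized counts.

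Of 11828 genes tested with limma, 7750 passed an adjusted p of 0.05, 3902 higher and 3848 lower with 4-OHT. At least 2-fold changes were found in 1537 genes, 1198 higher and 339 lower. In 8365 genes, 70.7% of those tested, the 3 values of one group all lay above the 3 of the other, where chance gives 10%. The direction of small changes depends on scaling, since dividing by total counts moved the median of all genes by -0.30 on the log2 scale and gave 2259 genes higher and 6549 lower, and among at least 2-fold changes 901 higher and 1057 lower. The p-values measure only the spread between these samples, since the labels do not say that the replicates were separate cultures. Log2 changes below are of normalized counts plus 1, which understates the change of genes with few vehicle reads.

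**Figure D1:**
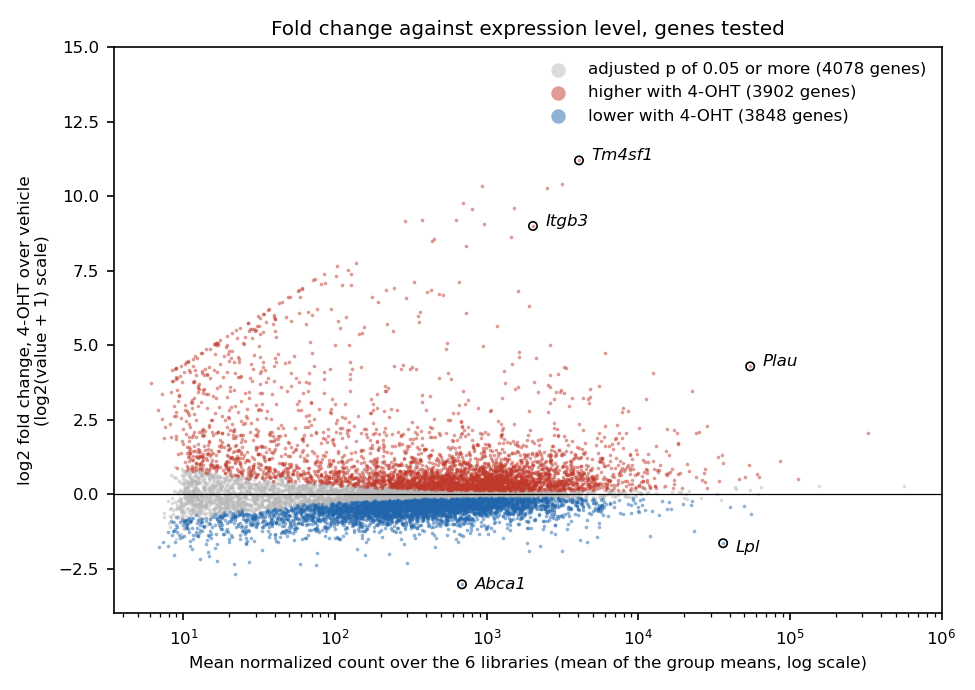
Log2 fold change of 4-OHT over vehicle (vertical axis) against the mean normalized count over the 6 libraries on a log axis (horizontal) for the 11828 genes tested, each point a gene, red where higher, blue where lower and grey where not called. Among genes past the adjusted p threshold, 1198 lie at a log2 change of 1 or more and 339 at -1 or less.

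The 12 most induced abundant genes had log2 changes from 8.55 to 11.20, with a largest adjusted p of 5.04e-09. Tm4sf1 (ENSMUSG00000027800.14, chromosome 3, 57285611 to 57301988, GRCm38/mm10), a tetraspanin-like membrane protein, rose from 2.35 ± 0.501 to 8129 ± 2585 normalized counts, a log2 change of 11.20 ± 0.21 (SE, adjusted p = 1.71e-11). Plxna4, a semaphorin receptor (ENSMUSG00000029765.12, chromosome 6, 32144268 to 32588192), rose 1566-fold, or 2433-fold without vehicle replicate A. The integrin subunits Itgb3 and Itga3 rose 585-fold and 454-fold, and Itgb3 (ENSMUSG00000020689.4, chromosome 11, 104608000 to 104670476) went from 6.89 ± 1.00 to 4034 ± 553 normalized counts. Afap1, which binds actin filaments, rose 978-fold, Tmem132b 1107-fold, and Cyp11a1, the enzyme that begins steroid hormone synthesis from cholesterol, 630-fold. With 5 and 10 vehicle reads these folds were imprecise, at 2234-fold for Tmem132b without vehicle replicate A and 1214-fold for Cyp11a1 without vehicle replicate B. Klhl3, a substrate adaptor of a ubiquitin ligase, had 0 vehicle reads and 1559 reads with 4-OHT, at least 663-fold higher against a floor of 3 reads over the vehicle group. Mcpt1, a mast cell protease, had 2 vehicle reads, both in replicate A, and 4989 reads with 4-OHT, a ratio of 3187 (95% exact binomial interval 882 to 26321), and Stfa2, a cysteine protease inhibitor, 1 and 2008 reads, a ratio of 2565 (460 to 101371). Skint7 rose 853-fold, or 1740-fold without vehicle replicate B, and Pfpl 578-fold, or 1044-fold without vehicle replicate A. Mcpt1, Stfa2, Skint7 and Pfpl have close relatives in the genome, and how shared reads were assigned is not stated. These intervals and floors cover counting error only.

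Among the most reduced abundant genes, the 11 reported here had log2 changes from -3.03 to -1.64, with a largest adjusted p of 8.42e-07. Abca1 (ENSMUSG00000015243.4, chromosome 4, 53030787 to 53159895) changed by -3.03 ± 0.11 (SE, adjusted p = 2.03e-09). Abcg1, which also exports cholesterol, changed by -1.92 ± 0.08. Lpl, lipoprotein lipase (ENSMUSG00000015568.16, chromosome 8, 68880491 to 68907448), fell from 54949 ± 1872 to 17592 ± 1353 normalized counts, a log2 change of -1.65 ± 0.08. Ephx1, microsomal epoxide hydrolase, fell to 0.241 times its vehicle level, and Hdac9, a histone deacetylase, to 0.246 times. The receptors Cx3cr1 (fractalkine) and Clec12a (an inhibitory C-type lectin) changed by -1.77 and -1.64. Rassf4, Fgf13, Fnbp1l and Cep68 made up the rest, at -1.91, -1.84, -1.74 and -1.67. Each gene named here among the largest rises and falls kept an adjusted p under 0.05 in every alternative run. All had been picked among called genes whose groups did not overlap, which favours this outcome.

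**Figure D2:**
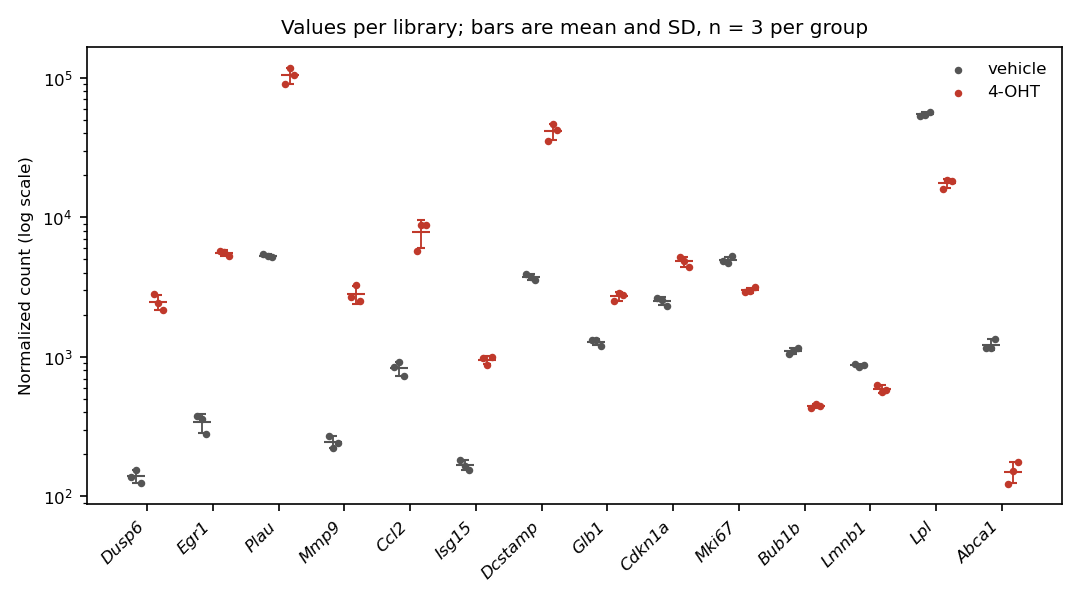
Normalized counts on a log axis for 14 named genes in the 3 vehicle and 3 4-OHT libraries, with the mean and SD of each group (n = 3). Plau lies at 5300 with vehicle and 104055 with 4-OHT, and Abca1 at 1225 and 151.

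Of 28 gene lists fixed before the data were examined, 24 had 3 or more tested genes, and 13 of these moved relative to the other genes by camera with a preset correlation of 0.01, 7 higher and 6 lower. With a correlation estimated from these samples, 0 of the 24 lists passed by camera, 3 of them at an unadjusted p under 0.05, whereas fry, which asks whether the genes of a list move one way without comparing them with other genes, passed 17. Counts adjusted over the list alone were the same as those over all genes in 23 of the 27 lists with a tested gene, and the other 4 are given with their lists. Counts and medians cover tested genes only. A member with few vehicle reads was tested only if it had enough reads with 4-OHT. This favours rises in lists with many rarely expressed members, such as the secretory, M1-like and dendritic cell lists.

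**Figure D3:**
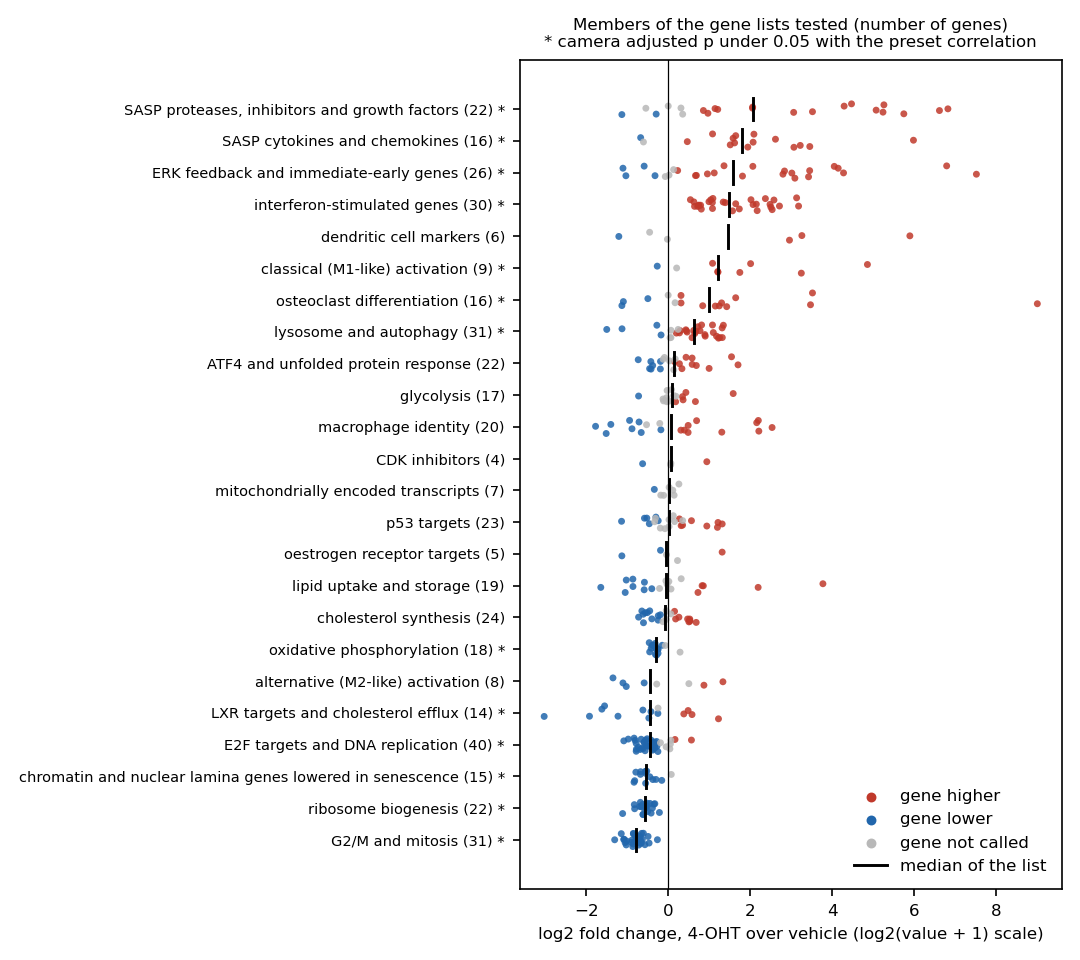
Log2 fold change of 4-OHT over vehicle (horizontal axis) for each gene of the 24 lists tested (vertical axis), red where higher, blue where lower and grey where not called, with the list median as a bar and a star where camera with the preset correlation passed. All 31 tested mitosis genes lie below 0 and all 30 interferon-stimulated genes above it.

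Of 26 ERK feedback and immediate-early genes, which ERK signalling induces, 19 were higher, 4 lower and 3 not called, over all genes and adjusted over the list alone, with a median log2 change of 1.58. The list passed at adjusted p = 3.94e-05, but not with an estimated correlation (adjusted p = 0.433 with an estimated correlation). Egr1, an immediate-early transcription factor, rose 16.4-fold, Epha2, an ephrin receptor, 126-fold, and Ier3 10.6-fold. The ERK pathway antagonists Spry2 and Dusp4 rose 7.18-fold and 2.17-fold, the transcription factor Etv4 4.43-fold and cyclin D1 (Ccnd1) 1.95-fold. Egr2 and Myc fell, by 1.10 and 0.59 on the log2 scale, and so did Fos and Etv5, chosen after their values were seen, at -1.03 and -0.32.

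All 31 tested genes of G2/M and mitosis were lower, over all genes and adjusted over the list alone, 7 of them at least 2-fold, with a median of -0.79 (adjusted p = 1.17e-11; adjusted p = 0.293 with an estimated correlation). Ccna2 (cyclin A2), Anln (anillin), Top2a (DNA topoisomerase II alpha) and the proliferation marker Mki67 changed by -1.15, -1.03, -0.85 and -0.71. Among 40 E2F targets and DNA replication genes, 33 were lower, 2 higher and 5 not called, over all genes and adjusted over the list alone, against 38 lower and 1 higher under total-count scaling, with a median of -0.46 (adjusted p = 7.12e-07; adjusted p = 0.395 with an estimated correlation). The replicative helicase subunits Mcm6 and Mcm7 changed by -0.81 and -0.68, Uhrf1, which maintains DNA methylation, by -0.83, and Rrm1, a ribonucleotide reductase subunit, by -0.53.

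All 22 ribosome biogenesis genes were lower, over all genes and adjusted over the list alone, with a median of -0.56 (adjusted p = 1.17e-07; adjusted p = 0.345 with an estimated correlation). Dkc1, the pseudouridine synthase dyskerin, changed by -1.11, and Wdr12, Nolc1 and Gnl3 by -0.70, -0.67 and -0.62. Of 15 chromatin and nuclear lamina genes known to be lowered in senescence, 14 were lower and 1 was not called, over all genes and adjusted over the list alone, with a median of -0.55 (adjusted p = 0.000126; adjusted p = 0.345 with an estimated correlation). The B-type lamins Lmnb1 and Lmnb2 changed by -0.55 and -0.82, the chromatin protein Hmgb2 by -0.84 and Cbx5 (HP1 alpha) by -0.79. Nuclear genes of oxidative phosphorylation were lower in 16 of 18 cases and not called in 2, over all genes and adjusted over the list alone, with a median of -0.31 (adjusted p = 0.000294; adjusted p = 0.395 with an estimated correlation). The respiratory chain subunits Ndufv1 and Sdha changed by -0.47 and -0.42.

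Cdkn1a, which encodes the CDK inhibitor p21, rose 1.92-fold, from 2519 ± 171 to 4834 ± 389 normalized counts (adjusted p = 3.84e-07). Cdkn2c (p18) changed by -0.63, and Cdkn1b (p27), at 0.06, and Cdkn2d (p19), at 0.06, were not called, Cdkn1b being lower, at -0.25, under total-count scaling. Cdkn2a and Cdkn2b were listed at 0 reads in all 6 libraries. So were S100a9 and 6 mitochondrially encoded genes, chosen after their values were seen, so a 0 in this table can also mark a gene whose reads were not counted. As a list the 4 tested CDK inhibitors were 1 higher, 1 lower and 2 not called, over all genes and adjusted over the list alone, against 1 higher and 2 lower under total-count scaling (median 0.06, or -0.24 under total-count scaling; adjusted p = 0.928). Of 23 p53 targets, 8 were higher, 6 lower and 9 not called, over all genes and adjusted over the list alone, against 5 higher and 11 lower under total-count scaling (median 0.02; adjusted p = 0.762). Plk2, Mdm2 and Pmaip1, a kinase, the p53 ubiquitin ligase and the pro-apoptotic protein Noxa, rose 2.49-fold, 2.32-fold and 2.30-fold. Trp53 itself changed by -0.25 (adjusted p = 0.0014).

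Genes of the senescence-associated secretory phenotype stood in a pair of lists. Of 24 cytokines and chemokines 16 were tested, and 14 were higher, 1 lower and 1 not called. Adjusted over the list alone 14 were higher and 2 lower, and under total-count scaling 13 were higher and 2 lower. The median was 1.79 (camera adjusted p = 4.12e-05, or 0.395 with an estimated correlation). Csf3 (granulocyte colony-stimulating factor) rose 68.1-fold and Ccl2, a monocyte chemoattractant, 9.45-fold, from 828 ± 95.3 to 7818 ± 1800 normalized counts. Ccl3, Il1rn (the interleukin-1 receptor antagonist), Ccl4 and Tnf rose 4.24-fold, 4.20-fold, 3.06-fold and 2.10-fold. Il1a, Il1b and Il6 were not tested, with 2, 9 and 2 vehicle reads and 3, 17 and 6 reads with 4-OHT over 3 libraries each. Of 36 proteases, inhibitors and growth factors 22 were tested. Of these, 16 were higher, 2 lower and 4 not called, over all genes and adjusted over the list alone. Under total-count scaling 16 were higher and 4 lower. The median was 2.05 (camera adjusted p = 2.48e-05, or 0.395 with an estimated correlation). Mmp9, a matrix metalloproteinase, rose 11.5-fold, Hbegf, an EGF receptor ligand, 115-fold, and Plaur, the urokinase receptor, 8.42-fold.

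All 30 tested interferon-stimulated genes were higher, over all genes and adjusted over the list alone, 21 of them at least 2-fold, with a median of 1.48 (adjusted p = 1.17e-11; adjusted p = 0.345 with an estimated correlation). Isg15, a ubiquitin-like modifier, rose 5.68-fold, Oasl1 5.16-fold, the RNA sensor Ifih1 4.43-fold and the transcription factor Irf7 3.33-fold. Of 16 classical (M1-like) activation genes 9 were tested. Of these, 7 were higher, 1 lower and 1 not called, over all genes and adjusted over the list alone. The median was 1.21 (camera adjusted p = 0.0132, or 0.345 with an estimated correlation). Socs3, a cytokine signalling inhibitor, rose 29.7-fold, Ptgs2 (cyclooxygenase-2) 9.27-fold, the costimulatory ligand Cd80 4.05-fold and Nos2 (inducible nitric oxide synthase) 2.37-fold, from 44 to 78 reads. Of 16 alternative (M2-like) activation genes 8 were tested. Of these, 2 were higher, 4 lower and 2 not called, over all genes and adjusted over the list alone. The median was -0.44 (camera adjusted p = 0.553), and under total-count scaling 1 was higher and 5 lower. Clec7a, the beta-glucan receptor dectin-1, changed by -1.35 and Il4ra by 1.33, and Arg1 had 2 reads in each group and was not tested.

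Of 31 lysosome and autophagy genes, 23 were higher, 4 lower and 4 not called, over all genes and adjusted over the list alone, against 18 higher and 7 lower under total-count scaling, with a median of 0.62 (adjusted p = 0.000343; adjusted p = 0.433 with an estimated correlation). Glb1, the lysosomal beta-galactosidase, rose 2.11-fold, from 1285 ± 67.9 to 2714 ± 189 normalized counts, the cholesterol exporter Npc1 2.34-fold, the autophagy receptor Sqstm1 2.38-fold and the protease Ctsd 2.51-fold. Mitf, a transcription factor of lysosomal genes, fell by 1.13 on the log2 scale, and Tfeb, a related factor chosen after its value was seen, fell from 244 ± 18.2 to 85.4 ± 0.627 normalized counts. Of 16 osteoclast differentiation genes, 11 were higher, 3 lower and 2 not called, over all genes and adjusted over the list alone, with a median of 0.99 (adjusted p = 0.00927; adjusted p = 0.433 with an estimated correlation). Besides Itgb3, Dcstamp, needed for cell fusion, rose 11.1-fold and the chloride transporter Clcn7 2.70-fold. Nfatc1, a transcription factor required for osteoclast formation, and Atp6v0d2, a proton pump subunit, fell by 1.13 and 1.10 and were chosen after their values were seen.

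Of 14 LXR targets and cholesterol efflux genes, 9 were lower, 4 higher and 1 not called, over all genes and adjusted over the list alone, against 10 lower and 2 higher under total-count scaling, with a median of -0.45 (adjusted p = 0.0387; adjusted p = 0.513 with an estimated correlation). Without 4-OHT replicate A the list did not pass (adjusted p = 0.0704), nor with a block for the replicate letter (0.0502) or under total-count scaling (0.165), and over all alternatives its adjusted p lay between 0.000273 and 0.513. Beside Abca1 and Abcg1, Scd1, a fatty acid desaturase, fell by 1.55 on the log2 scale, whereas Npc1, also in this list, rose by 1.22. Of 24 cholesterol synthesis genes, 9 were higher, 11 lower and 4 not called, over all genes and adjusted over the list alone, against 6 and 14 under total-count scaling (median -0.09; adjusted p = 0.553). Stard4, a cholesterol carrier, and Nsdhl, an enzyme of the pathway, changed by -0.72 and -0.40. Of 19 lipid uptake and storage genes, 5 were higher, 8 lower and 6 not called, and adjusted over the list alone 5 were higher and 9 lower, against 5 higher and 13 lower under total-count scaling (median -0.06, mean 0.08; adjusted p = 0.762, the camera direction being lower and that of fry higher). Fabp4, a fatty acid binding protein, rose 13.5-fold, the scavenger receptor Colec12 4.58-fold and the lipid droplet protein Plin2 1.77-fold. Lpl, also in this list, changed by -1.65 on the log2 scale. Cd36 was not called at 0.07 (0.17 with adjusted p = 0.0103 without 4-OHT replicate A, and -0.24 under total-count scaling). Over all alternatives the adjusted p of Cd36 lay between 0.00751 and 0.951.

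Of 20 macrophage identity genes, 10 were higher, 8 lower and 2 not called, and adjusted over the list alone 10 were higher and 10 lower, against 6 higher and 10 lower under total-count scaling (median 0.06; adjusted p = 0.928). Ccr2, the receptor of Ccl2, rose 5.82-fold and Itgam (CD11b) 4.63-fold, and Tlr2, a sensor of bacterial lipoproteins, changed by -0.94. Glycolysis genes were 6 higher, 1 lower and 10 not called of 17, over all genes and adjusted over the list alone, against 2 higher and 10 lower under total-count scaling (median 0.08; adjusted p = 0.423). The glucose transporter Slc2a1 rose 3.00-fold and hexokinase 1 (Hk1) 1.58-fold, and the lactate transporter Slc16a1 changed by -0.72. Of 22 genes of ATF4 and the unfolded protein response, 10 were higher, 7 lower and 5 not called, and adjusted over the list alone 11 were higher and 7 lower, against 6 higher and 12 lower under total-count scaling (median 0.14; adjusted p = 0.556). The cystine transporter Slc7a11 rose 2.93-fold and Ddit3 (CHOP) 1.98-fold, and Shmt2, a mitochondrial enzyme of serine metabolism, changed by -0.73.

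Of the 7 mitochondrially encoded transcripts tested, mt-Nd6 changed by -0.34 and 6 were not called, over all genes and adjusted over the list alone, against 5 lower under total-count scaling (median 0.02, mean -0.02; adjusted p = 0.956). Under 7 alternatives each, mt-Nd5, at -0.18, and mt-Co1, at 0.26, were called, mt-Nd5 with a block for the replicate letter (adjusted p = 0.0339) and mt-Co1 by DESeq2 (adjusted p = 3.93e-05), and both without 4-OHT replicate A (0.0371 and 0.0241). Over the alternatives that called them the adjusted p lay between 0.000102 and 0.0371 for mt-Nd5 and between 3.93e-05 and 0.0241 for mt-Co1, and mt-Nd1, at 0.14, was called under 3. Esr1 was not called at 0.22 ± 0.18 (SE, adjusted p = 0.282), and without 4-OHT replicate A it was called at 0.46 (adjusted p = 0.0041, the lowest over the alternatives, the highest being 0.728). Reads of the construct were not separated from those of Esr1. Of 5 oestrogen receptor targets, 1 was higher, 2 lower and 2 not called, over all genes and adjusted over the list alone (median -0.04, mean 0.03; adjusted p = 0.928, the camera direction being lower and that of fry higher). The higher gene was Ctsd, and Igfbp4, which binds insulin-like growth factors, changed by -1.13.

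Of 11 dendritic cell markers 6 were tested. Of these, 3 were higher, 1 lower and 2 not called, over all genes and adjusted over the list alone. The median was 1.47 (camera adjusted p = 0.553), and under total-count scaling 3 were higher and 2 lower. The class II gene H2-Aa had 2 vehicle reads, both in replicate C, and 216 reads with 4-OHT, a ratio of 138 (95% exact binomial interval 37.7 to 1147), H2-Ab1 had 10 and 96 reads and Xcr1 5 and 42, and the integrin Itgax changed by -1.21. The neutrophil marker S100a8 had 4 and 121 reads, and the endothelial markers Kdr and Cdh5 had 6 and 93 reads, and 10 and 77 reads. Among lymphocyte markers, Ighm, the IgM heavy chain, changed by -2.37, from 425 to 63 reads. From the fibroblast list 0 genes had enough reads to be tested. Spp1 (osteopontin), a secreted protein chosen after its value was seen, took 1.09% ± 0.0144 of the reads with vehicle and 3.69% ± 0.509 with 4-OHT (SD, n = 3), and the 10 most abundant genes took 10.7% ± 1.20 and 13.7% ± 0.842.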

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

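The alternatives chosen after the data were seen are the other scalings, the other pseudocounts, limma without the trend, camera with a mean-variance trend, and the edgeR fits on recovered reads (with all libraries, with the replicate block and without vehicle replicate B). Over 21 alternatives the number of genes changed by 4-OHT lay between 6395 (adjusted p under 0.01) and 8808 (total-count scaling), against 7750. On recovered reads edgeR called 7731 genes, DESeq2 7028 and voom 7721, and edgeR without vehicle replicate B 7095. Leaving out each library in turn gave 6979 to 7810 genes. Of the 7026 genes past an adjusted p of 0.05 in the authors' table, 6623 were called here in the same direction. Total-count scaling moved the median of all genes down by construction, since deposited totals are higher with 4-OHT, and gave 2259 genes higher, 6549 lower and 1057 lower at least 2-fold, with 63 calls reversed. It also turned the sign of Cdkn1b (-0.25) and Cd36 (-0.24), and Pgk1 no longer passed. With no filter, 23917 genes were tested rather than 11828, and 2471 changed at least 2-fold, 1982 of them higher. Of 123 named genes tested, 116 were called, 114 of these under every alternative, the exceptions being Pgk1 and Xbp1. The rule takes many of them as called genes or for a small p, so this share says little of calls at large. Of all 7750 calls, 6107 stayed called in the same direction under total-count scaling and 6625 by DESeq2. Without vehicle replicate B 6913 did, and with a pseudocount of 4, 7747.

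With an estimated correlation 0 of the 24 lists passed by camera (3 at an unadjusted p under 0.05), whereas fry passed 17; the cause was not tested. The adjusted p with an estimated correlation was 0.433 for the ERK, lysosome and osteoclast lists, 0.395 for E2F targets, both secretory lists and oxidative phosphorylation, 0.293 for mitosis, 0.513 for LXR targets, and 0.345 for interferon-stimulated genes, M1-like activation, ribosome biogenesis and the chromatin list. LXR targets also missed the threshold with a replicate block (adjusted p = 0.0502) and under total-count scaling (0.165), and leaving out each library gave 0.0259 to 0.0704, the highest without 4-OHT replicate A. The other 12 lists past the threshold passed under every alternative but the estimated correlation. By fry, which does not compare with other genes, p53 targets (0.00422), M2-like activation (0.000273), glycolysis (0.000743) and dendritic cell markers (0.00163) passed as well. With a replicate block the genes changed by 4-OHT numbered 7972. Deviations from the group mean correlated across genes by 0.11, 0.04 and 0.12 between libraries of the same letter, each library's highest with the other group. The principal component that took 2.90% of the variance also ordered both groups A, B and C. Its values were 6.88, 0.563 and -7.35 with vehicle and 17.4, -2.02 and -15.5 with 4-OHT. A batch shared by letter therefore cannot be excluded. The main fit, with group as its only term, does not allow for it. Depth limits what can be said of genes with few reads, such as Il1a, Il6 and Arg1, which were not tested.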

Other observations

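The search for gene families, the definition of related neighbours by the first 3 letters of their symbols, the tests that leave related neighbours out, the limit of 200 counts in each group, total-count and TMM scaling and edgeR on recovered reads were chosen after the data were seen. Among 358 families of gene symbols with 5 or more tested genes, examined for rises and falls of at least 2-fold (716 one-sided Fisher's exact tests), 9 passed an adjusted p of 0.05, all for rises. The test takes the genes of a family as independent of one another. Where they vary together its p-values are too small, and the families at 0.0480 lie close to the threshold. The dual-specificity phosphatases, many of which inactivate MAP kinases, rose at least 2-fold in 10 of 19 genes (adjusted p = 0.00244, and 7 genes under total-count scaling), among them Dusp14 (log2 change 3.85), Dusp2 (2.59) and Dusp8 (1.06). Guanylate-binding proteins, interferon-induced GTPases, rose in 6 of 7 genes (adjusted p = 0.00244), with Gbp2 at 3.13, Gbp3 at 2.18 and Gbp5 at 1.44, and all 5 Ifit genes rose (adjusted p = 0.00252), with Ifit3 at 2.71 and Ifit1 at 2.48. Semaphorins, secreted or membrane guidance proteins that bind plexins, rose in 6 of 11 genes (adjusted p = 0.0480), and Sema3c, Sema6d and Sema3e had log2 changes of 7.01, 6.67 and 5.63. The remaining families, each at adjusted p = 0.0480, were the Ccl chemokines (5 of 8), olfactory receptors (5 of 8, or 3 under total-count scaling), Ifi genes (7 of 16, or 4), microRNA host genes and microRNAs (6 of 12, or 5, with Mir155hg at 3.18) and genes with CD names (14 of 53, or 11). A gene with few vehicle reads passes the filter on low counts only if it has enough reads with 4-OHT. This favours rises among the tested members of rarely expressed families such as the olfactory receptors. Cd93 rose by 6.12, Cd200 by 4.26 and Cd274, the ligand of PD-1, by 1.24. All genes named here were chosen after their values were seen.

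Outside the lists, the selectins Sele and Selp, which bind leukocytes to endothelium, had 0 vehicle reads and 197 and 119 reads with 4-OHT, at least 84.0-fold and at least 50.7-fold higher. The class II gene H2-Eb1 rose from 17 to 1567 reads, a log2 change of 6.58. Olfr32 had 0 vehicle reads and 194 with 4-OHT, at least 82.4-fold higher. These genes were chosen after their values were seen.

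More genes rose than fell at least 2-fold, 1198 against 339, or 77.9% higher. Size factors that sit too high in the vehicle libraries stay open: under total-count scaling 46.0% of such genes were higher (95% exact binomial interval 43.8 to 48.3), but a shift shared by all genes lowers this share by construction and Spp1 alone took 3.69% of reads with 4-OHT against 1.09%, while TMM scaling gave 79.0%, edgeR 78.7% and DESeq2 82.6%. The edgeR fit uses TMM scaling, and DESeq2 scales as the deposited values do. All of these take most genes as unchanged or the changes as balanced, so their shares cannot decide the question. Genes near the count floor are argued against as the whole cause, since among genes with a mean of 200 or more normalized counts in each group 403 rose and 87 fell, 82.2% higher (78.6 to 85.5). A wider effect of the activated oncoprotein on transcription stays open and was not tested. The 10 splits of the 6 libraries are too few for a share under 0.05: the real split gave 1537 genes and 1 split, the real one, reached it, the highest other being 0 by limma, with 22 to 121 genes at an unadjusted p under 0.05 and 0 by edgeR. Every other split puts vehicle and 4-OHT libraries in both groups, which widens the spread within groups, so its 0 calls are no measure of chance.

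The mitosis, ribosome biogenesis and oxidative phosphorylation lists fell by small amounts in the same direction, with medians of -0.79, -0.56 and -0.31. A scaling error shared by all genes is argued against as the whole cause, since the highest percentile of the 3 medians among 10000 random lists matched on expression was 0.05. Such an error would move the random lists as well, so a share of it in the sizes of the falls stays open. A trend with GC content and transcript length, which explained 0.487% of the variance of log2 changes, is argued against as the whole cause, since after its removal the highest percentile was 0.22. These lists were already called lower by camera, and random lists ignore correlation between genes, so neither percentile is independent support for the falls. With an estimated correlation their adjusted p by camera lay between 0.293 and 0.395. No biological explanation was tested. The 10 splits are too few for a share under 0.05, with 13 lists past the threshold in the real split, the 1 split to reach it, and 11 in the highest other. Each other split called between 6 and 11 lists with 0 genes called, so these splits are no measure of chance for lists. For all genes the counts were 7750 for the real split, again 1 of 10, and 0 in the highest other by limma and by edgeR, against 8144 and up to 121 at an unadjusted p under 0.05.

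Genes raised at least 8-fold, 332 in number, often lay next to one another among tested genes, in 47 pairs against a mean of 9.33 in 10000 random placements (middle 95% up to 16; one-sided permutation p = 0.0001, the smallest these permutations can give), which argues against random placement. Reads shared between tandem copies of a gene stay open, with 32 pairs left without the 15 pairs of named genes that share their first 3 letters (random mean 8.97, middle 95% up to 15; one-sided permutation p = 0.0001, again the smallest). Among the 32 were 20 pairs with an unnamed gene model (random mean 1.78), 7 of them overlapping, and which of these models are copies of their neighbour was not determined, so overlapping models and joint regulation of neighbours stay open too. The other 12 pairs, of named genes with different first 3 letters, lay within the random range (mean 7.19, middle 95% up to 13, one-sided permutation p = 0.058). Among named genes, the excess therefore lay mainly in the 15 pairs with alike names (random mean 0.356). They include pairs of the Mcpt, Skint and Psg families, but also H2-Ab1 with H2-Aa, Mmp3 with Mmp10 and Sele with Selp. Which of them are copies close enough to share reads was not determined, so how much of the excess shared reads could account for is not known. The count compares names and measures no shared reads, so joint regulation of related neighbours would give the same result. A first definition of unrelated names, symbols that differ before the final number, gave 16 pairs (middle 95% up to 13, one-sided permutation p = 0.0028), but it counted Sele with Selp and H2-Aa with H2-Ab1 and H2-Eb1 as unrelated. The definition was changed after this result was seen, and the outcome among named genes depends on it.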
